A study of Danio rerio with 4 samples.

How the data were processed

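Single-cell RNA sequencing was done on whole testes of AB strain zebrafish males aged 3 months, with 1 library at each of ZT1, ZT7, ZT13 and ZT19. Per the labels' protocols, the testes were minced and digested with an enzyme for 30 min in RPMI1640 medium, and libraries were made with the 10x Genomics single cell 3' v3 kit, which tags each captured poly-A transcript with a unique molecular identifier (UMI). The light schedule, the number of animals per library and the dates or batches of preparation are not given in the sources used here. The authors deposited raw UMI counts per gene and cell barcode for each library, made with Cell Ranger 4.0 on the genome build GRCz11, per the submitters' processing notes; the annotation release and the settings are not given in the sources used here. The deposited counts are whole numbers with no normalization, and the lowest total of a listed barcode was 500 UMIs in each library. The barcode lists hold 30909 barcodes and the feature list 32057 genes, of which 1237 share their symbol with another identifier; 10 of the 551 genes on the fixed lists do so. Symbols and identifiers are those of the deposited feature list. No genome of this build was used here, so no coordinates are given.

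Barcodes were kept with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs; 130 had too few genes and 280 too many mitochondrial UMIs. Doublets were called in each library with scrublet, as run in scanpy 1.11.5, and removed: 289 at ZT1, 199 at ZT7, 194 at ZT13 and 266 at ZT19, which is 4.12%, 2.45%, 2.58% and 3.35% of the barcodes that passed. The 29655 kept cells had a median of 5567 UMIs and 2153 genes. Median UMIs per cell in the 4 libraries were 14157, 8977, 19022 and 12794 in spermatogonia-like cells, 7841, 5040, 7364 and 7329 in spermatocyte-like cells and 6891, 3996, 7549 and 2772 in spermatid-like cells. Pairs of libraries shared between 11 and 21 barcodes.

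Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 highly variable genes were chosen without the fixed list genes and mitochondrial genes, and the cells of all libraries were clustered together without batch integration on 30 principal components with 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Clusters were named from fixed markers of 17 cell classes. The marker lists were fixed before the data were examined, but the thresholds for giving a name were not: 2 forms of the naming rule were tried, and the one used was set after seeing which clusters it named. It asks for at least 3 markers at 2-fold or more above the median cluster and at 10 CPM or more, and for no other class with more than 50% as many markers unless at least 2 own markers and none of the rival class are among the 10 leading genes. No other class may have more markers among the 10 leading genes. A cluster whose depth was under 1/3 of its own libraries' stays unnamed unless an own marker is among its 10 leading genes. The first form had no such exception and judged depth by the library holding most of the cluster; under it cluster 3, with 2152 cells, is spermatocyte-like, and both Sertoli-like clusters are unnamed. Shares that moved under the first form are given in the closing section. Of the 2 spermatogonia-like clusters, cluster 6 rests on 3 markers with none among its 10 leading genes.

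For comparisons between classes, counts were summed per library and class where at least 20 cells were present, and a class needed such sums in 3 libraries. The sums were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM factors, the default filter on low counts, a library term as a block, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Genes used as clustering features were left out. Because each library is its own block, both classes of a pair come from the same library and sampling time. Standard errors were taken as the size of the log2 fold change divided by the square root of F. The comparison of Leydig-like with Sertoli-like cells was planned and not made, since Sertoli-like cells reached 20 in 1 library only. Camera set tests were run on 19 fixed gene lists with the preset and with an estimated correlation between genes.

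The rule for named genes, fixed before the data were examined, took list genes past the threshold with the same sign in every library: the 15 largest positive and 15 largest negative changes and up to 4 members per list with the smallest p. It named 90 genes in the first comparison and 84 in the second, of which the report gives a part; some genes that the rule took are not reported here. Over time it took the core clock and light-induced genes with at least 100 UMIs, the Leydig-like and Sertoli-like markers in their own class, and the 6 genes with the largest ratio between libraries among those with at least 200 UMIs, in all cells and in classes with at least 200 cells in every library. Genes named outside this rule are said to have been chosen after their values were seen.

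With 1 library per time no test was made across times. Values are CPM, the deposited counts scaled to equal library totals, with exact 95% Poisson intervals, and shares of cells carry exact Clopper-Pearson intervals; a count of 0 is given the limit of 3 counts. The 24 h amplitude and the 12 h component were computed from log2(CPM + 5), and a list's median amplitude was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A pseudocount understates the change of genes with few counts.

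The steps were tested on simulated data. For 15543 genes of the first comparison, 81.5% of genes changed 2-fold and 99% of genes changed 4-fold were recovered, with 4 and 9 false calls; for 13049 genes of the second, 60% and 99.5%, with 5 and 5 false calls. No call was made in either without a simulated effect. Where an effect was simulated, 200 genes were changed, up and down in equal number. All genes had a common dispersion, and both classes had the same library effect. In the data far more genes passed, so these false calls do not bound those in the data. Over time, with 18814 genes, 0, 19 and 20 of 20 simulated lists lay above the 95th percentile at log2 amplitudes of 0, 0.25 and 0.5. Every gene of a simulated list had the same rhythm, and the noise was independent between genes. Changes shared across genes were not simulated, so this does not bound the amplitude of a list in the data.

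Alternatives tried were DESeq2 1.42.0 with its own size factors, library totals without TMM, no filter on low counts, no library term, each library left out in turn, Leiden resolutions of 0.5 and 1.5, cells thinned to 1000 UMIs (which left out 458, 832, 575 and 949 cells), doublets kept, at least 1000 UMIs per cell, each gene centred per library, pseudocount 1, TMM factors over time, minima of 1 and 400 UMIs and equal weight to each germ cell class. Settings added after seeing the data were the first form of the naming rule and the shallow clusters kept in their class. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.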

Results

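Whole testes of 3-month-old AB strain zebrafish males were dissociated and profiled as single cells with 10x Genomics 3' v3 chemistry at 4 sampling times, ZT1, ZT7, ZT13 and ZT19. ZT is the usual abbreviation of zeitgeber time, counted in hours; the light schedule is not given in the sources used here. Each time is represented by 1 library, so a difference between times has no replicate check. The deposited UMI counts summed to 63830892 at ZT1, 49096889 at ZT7, 86743689 at ZT13 and 55158075 at ZT19, over 7083, 8158, 7684 and 7984 barcodes. After filtering, 6729, 7927, 7323 and 7676 cells remained, with a median of 6653, 4710, 8193 and 3719 UMIs per cell. The submitters' design text says that whole adult testes were profiled at the single-cell level, so the first question is which cells were recovered; the titles name the 4 times, which gives the comparison across the day.

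Most cells that could be named were germ cells. Spermatogonia-like cells, the mitotic germ cells that carry nanos2, ddx4 and dnd1 among their fixed markers, numbered 569 at ZT1, 869 at ZT7, 1073 at ZT13 and 360 at ZT19. Spermatocyte-like cells, in meiosis and named from genes such as sycp3, dmc1 and spo11, numbered 1597, 1486, 1946 and 1216. Spermatid-like cells, named from genes such as tssk6 and tekt1, numbered 544, 1194, 605 and 4210. Leydig-like cells, the androgen-producing cells of the interstitium, numbered 24, 20, 14 and 20, and Sertoli-like cells, which enclose the germ cells, 8, 25, 19 and 17. The remaining named cells were 27 fibroblast-like, 68 hepatocyte-like, 15 erythrocyte-like and 11 T or NK cell-like. The T or NK cell-like cluster, like several germ cell clusters given below, had none of its own markers among its 10 leading genes. The jun gene was among the 10 leading genes of 1 of the 2 Sertoli-like clusters.

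The spermatid-like share of kept cells was 8.08% at ZT1 (exact Clopper-Pearson 95% interval 7.44 to 8.76), 15.1% at ZT7 (14.3 to 15.9), 8.26% at ZT13 (7.64 to 8.92) and 54.8% at ZT19 (53.7 to 56.0). The spermatogonia-like share was 8.46%, 10.96%, 14.7% and 4.69%, and the spermatocyte-like share 23.7%, 18.7%, 26.6% and 15.8%. These too moved with the setting: at Leiden resolution 0.5 the spermatogonia-like share was 2.84%, 2.62%, 7.52% and 1.63%, and with genes centred per library it was 28.7% at ZT7. Hepatocyte-like cells made up 0.782% of the ZT19 library (0.597 to 1.005), 0.104% of ZT1 and 0.0126% of ZT7. None were found among the 7323 cells of ZT13, where the limit of 3 counts, and not the exact interval, allows a share of up to 0.041%. These intervals cover counting error only. Some clusters of the germ classes came mostly from 1 or 2 libraries: among spermatid-like cells clusters 20, 24 and 25 came almost entirely from ZT19, cluster 23 from ZT7 and cluster 10 from ZT1 and ZT13, and among spermatocyte-like cells cluster 13 came from ZT7, cluster 14 from ZT19 and clusters 2 and 4 mainly from ZT1 and ZT13. Spermatid-like cluster 7, with 194, 266, 172 and 998 cells, and both spermatogonia-like clusters held cells of all 4 libraries. Cluster 7, with 1630 cells, was itself shallow, at a median of 1037 UMIs and 0.221 of its libraries' depth. It kept its name through 1 own marker among its 10 leading genes, tssk6. A cluster made mostly of 1 library may be that library rather than a cell type.

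Unnamed cells made up 58.8% of ZT1, 54.6% of ZT7, 49.9% of ZT13 and 23.2% of ZT19. Shallow clusters 0, 1 and 21, which carried spermatid markers but had none among their 10 leading genes, took 28.3%, 12.8%, 12.9% and 2.45% of the 4 libraries. Named spermatid-like clusters 10, 20, 23, 24 and 25 and spermatocyte-like cluster 14 also had no own marker among their 10 leading genes. They kept their names because they were not shallow. Shallow clusters 3 and 12, which carried spermatocyte markers, took 8.20%, 7.96%, 5.08% and 10.1%. Clusters 8 and 19 carried markers of both spermatids and spermatocytes and took 8.31%, 20.3%, 11.9% and 0.795%, and cluster 11, with markers of both spermatocytes and spermatogonia, took 7.58%, 8.63%, 12.6% and 0.703%. Cluster 9 had under 3 markers of any class and took 5.90%, 4.09%, 6.91% and 2.38%. Cluster 17, whose best class was spermatogonia-like with 2 markers, took 0.0743%, 0.542%, 0.0546% and 6.46%, which at ZT19 is more than the named spermatogonia-like share. With the shallow clusters kept in their classes, the spermatid-like share was 36.3% at ZT1, 27.9% at ZT7, 21.2% at ZT13 and 57.3% at ZT19. With at least 1000 UMIs required per cell it was 6.47%, 1.198%, 4.91% and 21.3%. That setting also clusters and names the cells anew, and only 476 of the 4210 spermatid-like cells of ZT19 had under 1000 UMIs. The size of the ZT19 share thus depended on the setting, and no order of the 4 times is drawn from these shares. The thresholds that left these clusters unnamed were set after the clusters had been seen.

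**Figure D1:**
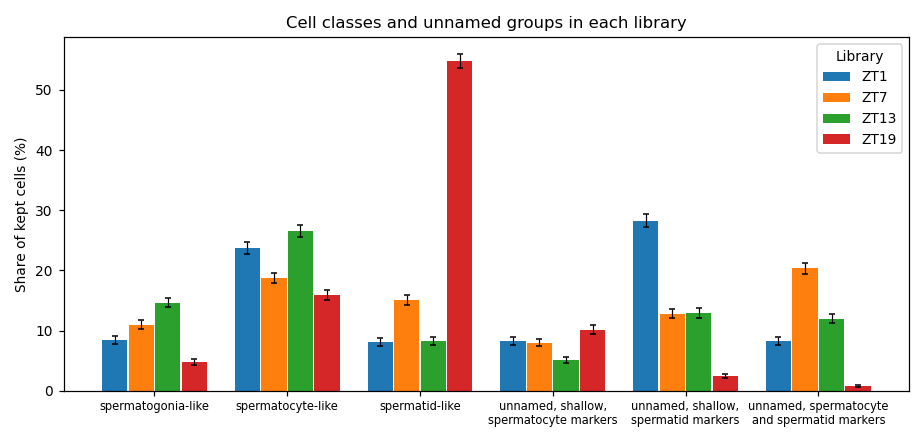
Share of kept cells, in percent on the vertical axis, in each of the 3 germ cell classes and in 3 unnamed groups of clusters, with 1 bar per library and exact 95% binomial intervals as error bars. The spermatid-like bar of ZT19 reaches 54.8%, while the unnamed shallow group with spermatid markers reaches 28.3% at ZT1.

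Spermatocyte-like cells differed from spermatogonia-like cells first in the genes of the flagellum. Of 46 tested genes of the axoneme and ciliary motility list, 45 were higher in spermatocyte-like cells, among them iqcg, a part of the dynein regulatory complex, with a log2 fold change of 4.70 ± 0.23 (SE, n = 4 libraries), and the dynein intermediate chain gene dnai2a, at 3.91 ± 0.17. All 24 tested genes of intraflagellar transport, the machinery that builds cilia, were higher, ift88 by 3.56 ± 0.15 and kif17 by 3.83 ± 0.21. The ciliary transcription factor gene foxj1b rose by 4.91 ± 0.18 and the spermiogenesis regulator cremb by 4.67 ± 0.18, from 35.4, 32.3, 31.9 and 51.8 CPM (UMI counts scaled to equal library totals) in spermatogonia-like cells at ZT1, ZT7, ZT13 and ZT19 to 673, 573, 974 and 785 CPM. The largest rise among named genes was that of eno4 (ENSDARG00000070598), an enolase-related gene of the glycolysis list, at 5.24 ± 0.21 and an adjusted p of 3.6e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

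Genes of meiotic recombination rose in the same comparison. The spermatocyte-like class was named from genes such as dmc1 and spo11, so part of this rise is built into the naming. Of 31 tested genes of homologous recombination repair, 21 were higher (22 adjusted over the list alone) and 5 lower (5 adjusted over the list alone). The DNA helicase gene hfm1 rose by 3.32 ± 0.14, while atm, chosen after its values were seen, fell by 0.73 ± 0.14. In the piRNA pathway, which silences transposons in germ cells, 8 of 14 genes were higher and 6 lower: the tudor domain gene tdrd5 fell by 2.45 ± 0.15, and mybl1, a transcription factor gene of male meiosis, rose by 2.66 ± 0.12. The median log2 fold change of this list was 0.40 and its mean -0.02, so the 2 differ in sign. Of the G2 and M phase list 18 of 23 genes were higher, cenpe by 2.57 ± 0.13 and cdk1 by 1.66 ± 0.11, and the 5 lower genes were all cyclin genes or cdc20, led by ccnb3, which fell by 2.11 ± 0.13. Of 22 S phase genes 6 were higher and 11 lower; orc6, a gene of the origin recognition complex, fell by 3.81 ± 0.18, and slbp, the histone stem-loop binding protein gene, rose by 1.197 ± 0.10.

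Clock and light-responsive genes were mostly lower in spermatocyte-like cells. Of 32 tested core clock genes 22 were lower and 4 higher, and of 11 light-induced genes 10 were lower and 1 higher. The cryptochrome gene cry1a (ENSDARG00000045768), which is on both lists, fell by 4.598 ± 0.21, from 19.5, 26.3, 17.1 and 18.4 CPM to 0.531, 1.08, 0.519 and 0.573 CPM, and ddb2, a DNA damage recognition gene, fell by 4.38 ± 0.18. The clock repressor genes nfil3 and nfil3-5 fell by 2.50 ± 0.20 and 1.79 ± 0.17. The 4 higher clock genes, chosen after their values were seen, were cry4 at 0.72 ± 0.14, per2 at 0.86 ± 0.20, dbpa at 1.12 ± 0.31 and nr1d1 at 1.06 ± 0.42; per2, also the higher gene of the light-induced list, and nr1d1 were higher in 3 of 4 libraries. In the other temperature and stress lists, cirbpb, a cold-inducible RNA-binding protein gene, fell by 1.75 ± 0.09 among 3 lower and 2 higher of 6 temperature-responsive genes, and 9 of 28 dissociation and stress genes were higher and 12 lower, with the endoplasmic reticulum chaperone gene hspa5 rising by 1.51 ± 0.14 and egr2a falling from 3.01, 7.84, 4.57 and 6.27 CPM to 0.404 CPM or less.

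Metabolic and signalling lists went both ways. Glycolysis genes were higher in 13 and lower in 9 of 27, with tpi1a rising by 2.50 ± 0.10 and the aldolase gene aldoaa falling by 3.29 ± 0.12 (log2 -3.29). Oxidative phosphorylation genes were higher in 23 and lower in 7 of 40; the subunit gene cox6b2 rose by 1.49 ± 0.08, while cox6b1 fell by 3.76 ± 0.40, with a far smaller difference at ZT7 than in the other libraries. Cholesterol synthesis genes were higher in 9 and lower in 7 of 23, hmgcs1 rising by 2.01 ± 0.11, and retinoid metabolism genes were higher in 2 and lower in 5 of 11, the retinol transporter gene stra6 rising by 1.96 ± 0.13 and rbp5 falling from between 7.93 and 14.8 CPM to between 0.677 and 1.15 CPM. Steroid and gonadotropin receptor genes were higher in 5 and lower in 9 of 15, with the estrogen receptor gene esr2b at 3.61 ± 0.40 and the thyroid hormone receptor gene thrb at -4.49 ± 0.27. Germ-soma signal genes were higher in 6 and lower in 16 of 29: gdnfb rose by 3.42 ± 0.23 and the Notch ligand gene jag2b fell by 3.49 ± 0.22. Extracellular matrix genes were higher in 1 and lower in 9 of 14, with timp2a at -4.97 ± 0.27 and below 0.4 CPM in every spermatocyte-like sum. Of 89 genes taken by the ribosomal protein name pattern 12 were higher and 57 lower, rps3a falling by 1.23 ± 0.09 (log2 -1.23) and rplp2 rising by 1.01 ± 0.07; the pattern also takes 11 S6 kinase genes, which encode kinases and not ribosomal proteins, and 1 of them, rps6ka1, had the second largest fall of all named genes, -4.74 ± 0.26. Of 15 regulators of ciliogenesis and spermiogenesis 10 were higher and 3 lower.

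Over all 15543 genes tested, 5789 were higher and 6169 lower in spermatocyte-like cells by edgeR's quasi-likelihood test with the library as a block, at an adjusted p under 0.05. Genes used to form the clusters were left out, but the classes were still made from expression, so many of these differences are built into the classes. The rule for named genes also took tdrd1, mcm3 and mcm4 here and tm7sf2 and mcm6 in the next comparison, which lead clusters of the classes compared and are not given as results. In a camera set test with a preset correlation 9 of 19 lists passed, led by the axoneme list (adjusted p = 2.1e-27), and none passed with an estimated correlation (adjusted p = 0.447 or more), where 1 list had an unadjusted p under 0.05. The core clock list was among those lost, though its estimated correlation was -0.0019, so correlation between genes is not the whole reason. Other lists had high estimated correlations, 0.82 for axoneme, 0.88 for intraflagellar transport and 0.55 for ribosomal proteins. The preset form takes no account of these values, so its adjusted p can be far too small for such lists. With so few sums and a library term, the estimated form leaves few degrees of freedom, so its failures decide nothing about the lists. With library totals in place of TMM factors the median gene shifted by -0.35 on the log2 scale and the calls were 4502 higher and 7485 lower, a higher share of 37.6% against 48.4%. Under that scaling the cholesterol synthesis list had 8 higher and 9 lower, and no other list changed its majority. With every cell thinned to 1000 UMIs 8079 genes were tested, and 2723 were higher and 2950 lower.

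Spermatid-like cells, compared with spermatocyte-like cells, had lower levels of genes for DNA replication and recombination and higher levels of genes for the flagellum and for cell division. Of 22 S phase genes 20 were lower: the thymidylate synthase gene tyms (ENSDARG00000042894) fell by 3.84 ± 0.22 (SE, n = 4 libraries), from 96.9, 151, 80.8 and 128 CPM at ZT1, ZT7, ZT13 and ZT19 to 4.87, 6.51, 7.37 and 9.95 CPM, and pcna, the sliding clamp of replication, fell by 3.33 ± 0.21. The 1 higher S phase gene, chosen after its values were seen, was rrm2, which rose by 0.93 ± 0.16. Spermatocyte-like clusters 2 and 13 had pclaf and prim2 among their 10 leading genes, and cluster 2 also had mcm6 of the S phase list. How far the S phase fall depends on which clusters were named spermatocyte-like was not tested. Of 31 homologous recombination repair genes 20 were lower and 8 higher; rad51b fell by 3.71 ± 0.24 and mnd1 fell by 3.34 ± 0.21. All 46 tested axoneme genes were higher, among them the dynein heavy chain gene dnah9 at 3.22 ± 0.18 and zmynd10, a dynein assembly factor gene, at 2.68 ± 0.20. Of 24 intraflagellar transport genes 20 were higher and none lower, ift81 rising by 2.41 ± 0.21. Fixed spermatid-like markers such as tekt1 are flagellar genes, and spermatocyte-like markers such as dmc1 and spo11 are recombination genes. Part of the flagellar rise and of the recombination fall is thus built into the naming.

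Of 23 genes of the G2 and M phase list 21 were higher and none lower in spermatid-like cells, a class named from marker genes alone, without a measure of ploidy. How far this class holds dividing cells was not tested, so these values are not read as a trait of spermatids. The cyclin genes ccnb3 and ccna2 rose by 4.27 ± 0.31 and 3.83 ± 0.22, and the mitotic kinesin gene kif11 rose by 3.32 ± 0.20, from between 35.2 and 50.7 CPM to 537, 408, 445 and 268 CPM. The piRNA pathway was lower in 11 and higher in 2 of 14 genes, tdrkh falling by 2.81 ± 0.19 (log2 -2.81) and piwil2, which encodes a PIWI protein, by 2.02 ± 0.18 (log2 -2.02). Of 88 genes taken by the ribosomal pattern 81 were lower, rps26 by -3.07 ± 0.23 and rpl39 by -2.94 ± 0.24. Its 5 higher genes, chosen after their values were seen, were rps27l and rps8b and the S6 kinase genes rps6kb1a, rps6ka3b and rps6ka4. Oxidative phosphorylation genes were lower in 24 and higher in 1 of 40 (23 and 1 adjusted over the list alone), with atp5fa1, a subunit gene of ATP synthase, at -2.47 ± 0.21. Glycolysis genes were lower in 14 and higher in 4 of 26, with gpia at -2.86 ± 0.16 and its paralog gpib at 2.19 ± 0.22; reads shared between such near copies can blur each value.

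The largest single change among the named genes was in dlc (ENSDARG00000002336), a Notch ligand gene, which rose by 6.12 ± 0.30, from 0.664, 0.542, 0.404 and 0.477 CPM to 57.3, 42.5, 30.9 and 13.1 CPM. It stood among 8 higher and 7 lower of 18 germ-soma signal genes, with gdf9 at 4.05 ± 0.29 and bmp15 at -3.02 ± 0.37. Cholesterol synthesis genes were higher in 6 and lower in 9 of 21: pmvk, the phosphomevalonate kinase gene, rose by 3.72 ± 0.55, while hmgcs1 fell by 1.55 ± 0.17. Of 15 regulators of ciliogenesis and spermiogenesis 5 were higher (6 adjusted over the list alone) and 6 lower, with rfx3, a ciliary transcription factor gene, at 4.41 ± 0.32 and tbpl2 at -2.83 ± 0.23. Of 20 core clock genes 6 were higher and 11 lower: cry1b rose by 3.14 ± 0.24, dbpb by 3.00 ± 0.19 and cry3b by 1.40 ± 0.16 (0.85 at Leiden resolution 0.5, adjusted p 0.0956), and tefa fell by 2.08 ± 0.24. Light-induced genes were lower in 5 and higher in none of 10, neil1 at -2.13 ± 0.29. Temperature-responsive genes were lower in 4 of 6, cirbpa at -2.64 ± 0.20. Of 24 dissociation and stress genes 4 were higher and 6 lower, dnajb1b, a heat shock co-chaperone gene, rising by 2.81 ± 0.22. Retinoid genes were lower in 8 and higher in 1 of 9, with stra6 at -3.14 ± 0.23; the higher gene was rbp5, at 3.62 ± 0.55, with 45.8 CPM at ZT7 and 3.98, 4.63 and 17.0 CPM in the other spermatid-like sums. Receptor genes were higher in 7 and lower in 4 of 12, ghra at 3.14 ± 0.34, and extracellular matrix genes were higher in 2 and lower in 3 of 5, with a median of -0.79 and a mean of 0.01.

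Over all 13049 genes tested, 4098 were higher and 5291 lower in spermatid-like cells by edgeR's quasi-likelihood test with the library as a block. In the camera test with a preset correlation 8 of 19 lists passed, led by the ribosomal list (adjusted p = 4.7e-18), the axoneme list (5.6e-17), the S phase list (5.8e-13) and the G2 and M phase list (1.1e-09). None passed with an estimated correlation (adjusted p = 0.503 or more), where 1 list had an unadjusted p under 0.05. As in the first comparison, few degrees of freedom were left for that form, so its failures decide nothing about the lists. The estimated correlation was 0.69 for the ribosomal list, 0.69 for axoneme, 0.42 for S phase and 0.55 for G2 and M phase. Their adjusted p in the preset form can therefore be far too small. Library totals in place of TMM shifted the median gene by -0.12, and the germ-soma list then had 7 higher and 8 lower, with no other list changing its majority. Thinned to 1000 UMIs the calls were 2336 higher and 3079 lower, and at a lower clustering resolution 2478 were higher. The 4 libraries are the replicates of both comparisons, and the labels do not say how many animals went into each. With the library as a block, these p-values measure how the difference between classes varied from library to library. The libraries also differ in sampling time.

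**Figure D2:**
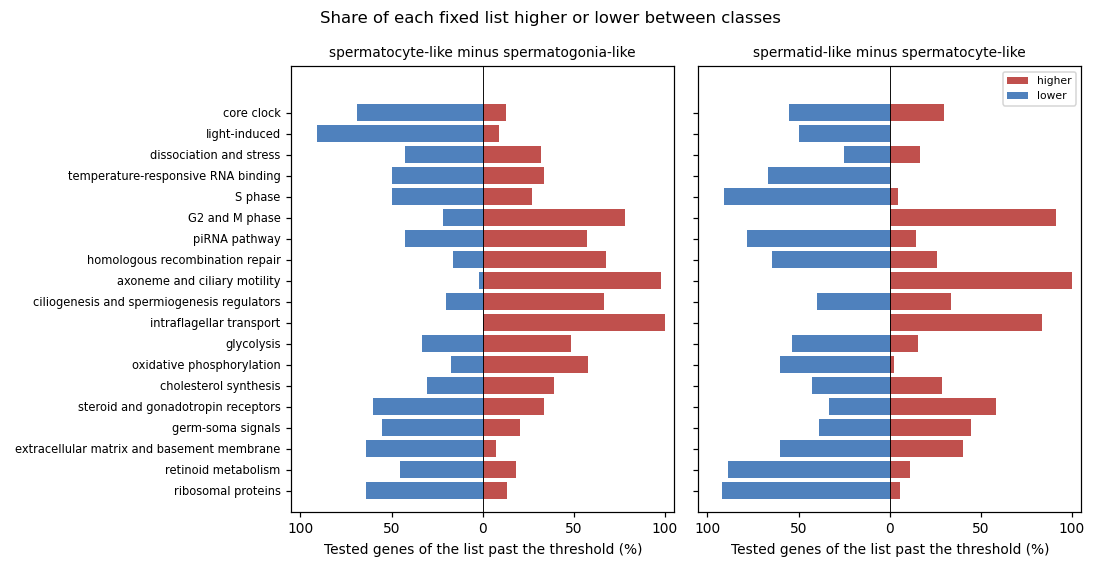
For each of the 19 fixed gene lists, the percentage of its tested genes that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, for spermatocyte-like minus spermatogonia-like cells on the left and spermatid-like minus spermatocyte-like cells on the right. The axoneme list is higher in both panels, with 45 and 46 of 46 genes; under library totals without TMM the majority turned for the cholesterol synthesis list on the left and the germ-soma signal list on the right.

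Leydig-like and Sertoli-like cells were too few to be compared by a test, since at least 20 Sertoli-like cells were found in 1 library only. Within Leydig-like cells insl3, the gene of an insulin-like hormone of the testis, took 225481 CPM at ZT1, 242054 at ZT7, 149993 at ZT13 and 149520 at ZT19. The steroidogenic enzyme gene cyp17a1 was at 6408 CPM at ZT1 (95% Poisson interval 6086 to 6742), 3149 at ZT7 (2894 to 3420), 2841 at ZT13 (2590 to 3109) and 1832 at ZT19 (1598 to 2092). The cholesterol carrier gene star was at 7840, 8196, 10124 and 6158 CPM and cyp11c1, the 11-beta-hydroxylase gene, at 2126, 2646, 2448 and 3447 CPM. The gonadotropin receptor gene lhcgr had no UMI at ZT1 and ZT7 and hsd3b2 none in any library, which at this depth does not show absence. In Sertoli-like cells gsdf, a growth factor gene of the TGF-beta family, was at 3845, 3108, 3730 and 1736 CPM, and amh, the anti-Müllerian hormone gene, at 305 (146 to 561), 519 (399 to 664), 386 (252 to 566) and 48.5 CPM (15.7 to 113). The dmrt1 gene was at 580, 115, 907 and 233 CPM. These are values of 1 library each from between 8 and 25 cells. The Poisson intervals cover counting error only. The Leydig-like cluster and both Sertoli-like clusters were named only through the exception for a rival class. Sertoli-like cluster 31 carried 7 hepatocyte markers beside 9 of its own, and cluster 27 carried 4 epithelial markers beside 6. Leydig-like cluster 16 carried 5 Sertoli markers beside 9 of its own.

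Across the 4 sampling times the core clock list did not stand apart in 24 h amplitude from other genes of like expression. Over all cells its 34 measured genes had a median 24 h amplitude of 0.14 on the log2 scale, against 0.12 for random lists, which is the 82.7th percentile of 10000 lists of the same size matched on mean expression. Within spermatogonia-like, spermatocyte-like and spermatid-like cells its percentile was 71.4, 19.7 and 28.3. In the 12 h component it was low over all cells, with a median of 0.06 against 0.09 for random lists, the 1.98th percentile, but its percentile was 30.3 with TMM factors and between 12.4 and 38.5 in the germ cell classes. ZT7 was the highest library for 16 of the 34 genes, with 9 highest at ZT13, 5 at ZT19 and 4 at ZT1. The 11 light-induced genes were at the 46.4th percentile, with 6 highest at ZT13 and 4 at ZT7, and their percentile was 96.2, 25.3 and 58.4 in the 3 germ cell classes in the same order. With 1 library per time no test was made and no p is given; with equal weight to the 3 germ cell classes the clock list was at the 6.87th percentile, and with cells thinned to 1000 UMIs at the 90.9th.

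The period gene per1b (ENSDARG00000012499) had the largest 24 h amplitude of the list, 0.53, with 14.4 CPM at ZT1 (13.4 to 15.3), 33.7 at ZT7 (32.1 to 35.4), 13.8 at ZT13 (13.1 to 14.7) and 13.5 at ZT19 (12.5 to 14.5). In spermatogonia-like cells it stood at 26.5, 52.7, 21.8 and 25.8 CPM, in spermatocyte-like cells at 12.5, 22.3, 11.4 and 12.5 CPM and in spermatid-like cells at 3.76, 7.24, 3.999 and 4.22 CPM, so ZT7 was the highest library in each class. At ZT7 per3, ciarta, cry1a, cry3a and dbpb were also highest over all cells: per3 at 7.94, 11.3, 6.99 and 7.01 CPM, ciarta at 33.6, 49.1, 34.5 and 27.3, cry1a at 9.35, 14.2, 10.2 and 7.24, cry3a at 32.4, 36.4, 32.7 and 26.2, and dbpb at 24.2, 38.0, 17.2 and 30.5 CPM. The genes cry1b and per1a were highest at ZT1, cry1b with 34.3, 25.5, 18.3 and 24.6 CPM and per1a with 14.4, 11.8, 8.09 and 8.19 CPM. The cry4 gene was at 38.6, 23.0, 27.2 and 39.3 CPM and cry2 at 14.2, 15.9, 16.7 and 10.1 CPM. The BMAL1 paralog arntl1a, a partner of CLOCK in the positive arm of the clock, was at 19.3, 13.5, 20.8 and 15.5 CPM, with a 12 h component of 0.18 that exceeded its 24 h amplitude of 0.09. Of the light-induced genes lonrf1l was at 9.42, 15.04, 11.03 and 9.93 CPM and ddb2 at 41.8, 27.4, 54.5 and 34.6 CPM.

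**Figure D3:**
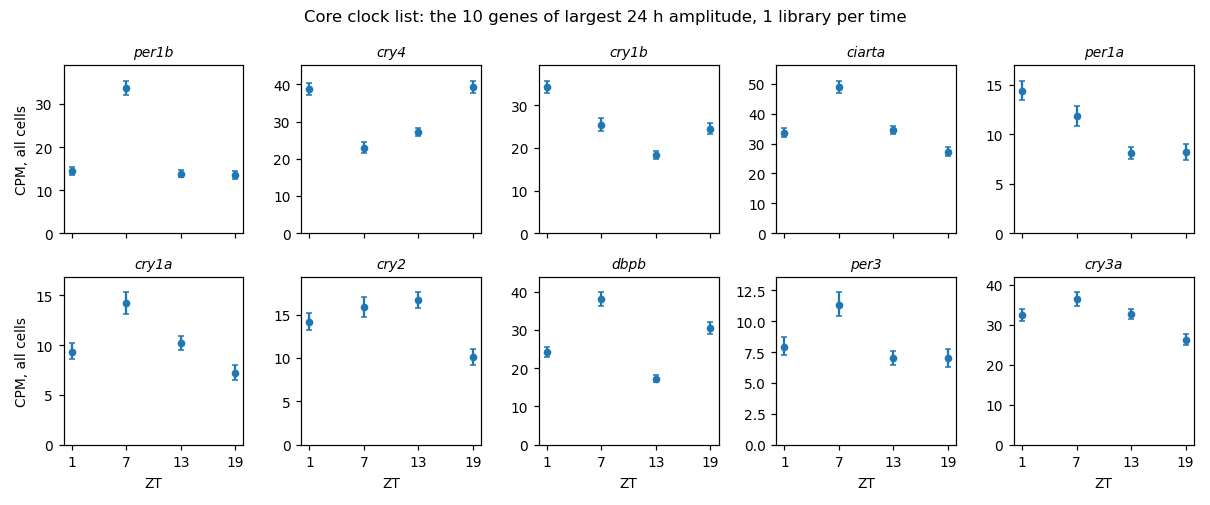
CPM over all cells (vertical axis) against sampling time in ZT hours (horizontal axis) for the 10 core clock genes with the largest 24 h amplitude, 1 library per point, with exact 95% Poisson intervals for counting error only. The per1b point at ZT7 lies at 33.7 CPM and the other 3 between 13.5 and 14.4 CPM.

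The genes with the largest ratio between libraries over all cells were all highest at ZT19, and 4 of the 6 were among the 10 leading genes of the hepatocyte-like cluster. The apolipoprotein gene apoa2 was at 159 CPM at ZT1, 6.88 at ZT7, 0.0966 at ZT13 and 655 at ZT19, apoa1b at 85.8, 3.19, 0.314 and 384 CPM, and fabp10a, a fatty acid binding protein gene of hepatocytes, at 54.7, 3.41, 0.109 and 330 CPM. The last of the 4 was si:ch211-270n8.1, known like the other genes, BX005351.1 and si:dkeyp-73d8.9, only by a clone name. In spermatid-like cells ribc1, which encodes a protein of ciliary microtubules, was at 255 CPM at ZT7 (242 to 269), 0.221 CPM at ZT1 and 0.201 CPM at ZT19, with no UMI at ZT13, and hdac9b, a histone deacetylase gene, was at 68.7 CPM at ZT7 and at or below 0.664 CPM elsewhere. In spermatocyte-like cells endou2 was at 112, 0.271, 61.4 and 55.2 CPM, ribc1 at 26.8 CPM at ZT7 against 0.289 CPM or less, and apoa2 at 29.4 CPM at ZT19 against 3.11 CPM or less. In spermatogonia-like cells slc22a13a, a solute carrier gene, was at 0.489, 26.6, 0.907 and 0.285 CPM, hhatlb at 13.6, 0.0871, 9.47 and 4.27, hbbe1.1, a haemoglobin gene, at 0.0815, 9.50, 6.53 and 5.13, zgc:91968 at 0.0815, 0.959, 9.76 and 1.99, and sult1st9, a sulfotransferase gene, at 9.12, 6.71, 0.145 and 4.41 CPM. In spermatid-like cells ccr11.1 was at 29.9, 5.06, 10.7 and 0.101 CPM. The rule's other genes in these classes are known only by clone names. The ribc1 gene leads the ZT7 cluster 23 of the spermatid-like class, so its level there and that cluster are not separate observations.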

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

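The splits of the samples were chosen as tests only after the counts of genes had been seen; the search for a library far from the others was planned.

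In 5 of 174 differences of named genes between classes, 1 library lay far from the other 3; chance marks about 1 in 20. All values are differences of log2(CPM + 1) within a library. For hfm1 in spermatocyte-like minus spermatogonia-like cells, ZT1 had 2.88 and the nearest library 2.75. For clockb in the same comparison, ZT13 had -2.44 and the nearest library -2.22. For cox6b1, ZT7 had -2.12 while the others lay between -4.38 and -4.63, with 26.1 CPM in spermatocyte-like cells at ZT7 and 3.05 to 3.75 CPM elsewhere. For ccna2 in spermatid-like minus spermatocyte-like cells, ZT7 had 4.29 and the others 3.47 to 3.51. For rbm4.1 in that comparison, ZT1 had -2.18 and the others between -1.01 and -1.20. ZT1 and ZT7 were far from the others 2 times each, ZT13 1 time and ZT19 0 times.

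The 8 sums of each comparison can be split into equal groups in 35 ways. Without the library block, the real split gave 10797 genes for spermatocyte-like minus spermatogonia-like cells and the highest other split 1; 1 of 35 splits, the real one, gave as many. For spermatid-like minus spermatocyte-like cells the real split gave 8270 and the highest other split 2, again with 1 of 35 as large. With the library block there are 8 within-library swaps, too few for a share under 0.05; the real counts were 11958 and 9389 and the highest other count 0 in both. Classes formed from expression differ in expression by construction, so the order of the splits was built in and these counts exclude nothing about chance.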

How the results depend on the processing

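The first form of the naming rule and the keeping of shallow clusters were added after the data were seen. Of the 90 named genes of spermatocyte-like minus spermatogonia-like cells, 87 kept their direction and side of the threshold in every setting in which they were tested. Of the 84 of spermatid-like minus spermatocyte-like cells 76 did. The settings with at least 1000 UMIs per cell and with genes centred per library were run for the shares only, not for these comparisons. The exception in direction was srsf7a in the first comparison, at 0.62, which was -0.051 with thinned cells (adjusted p by edgeR 0.74); the cause was not tested. In the second, lama1 was past the threshold at 1.04 and not without ZT1, at 0.86, nor at either other resolution or under the first naming form, and cry3b, at 1.40, was 0.85 at resolution 0.5 (adjusted p 0.0956); the causes were not tested. Leaving out 1 library gave 10907 to 12082 genes in the first comparison (5184 to 5899 higher, 5723 to 6183 lower) and 8213 to 9605 in the second (3567 to 4341 higher, 4460 to 5264 lower). Without the replicate block the counts were 10797 and 8270, within 1.5 times the blocked counts. Thinned cells gave 5673 genes (2723 higher, 2950 lower) and 5415 (2336 higher, 3079 lower), where fewer genes were tested; resolution 0.5 gave 2478 higher in the second comparison, and the cause was not tested. No alternative was run for Leydig-like minus Sertoli-like cells, and no amplitude can be had from 3 times.

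The clock list's percentile was 69.5 with pseudocount 1, 85.2 with TMM factors, 77.5 with a minimum of 1 UMI, 87.1 with 400 UMIs, 90.9 thinned and 6.87 with equal weight to the 3 germ cell classes; none reached the 95th. Its 12 h percentile, 1.98, was 0.84 with pseudocount 1, 0.53 with 400 UMIs, 3.54 thinned and 30.3 with TMM factors. Depth limits how many genes can be measured, as 20 of the 34 clock genes were with thinned cells. The causes of the moves of the shares were not tested. At resolution 0.5 the spermatogonia-like share at ZT1, ZT7, ZT13 and ZT19 was 2.84%, 2.62%, 7.52% and 1.63%, the spermatocyte-like share 30.2%, 28.2%, 29.2% and 25.5%, and the spermatid-like share 3.11%, 26.5% and 2.51% at the first 3 times. At resolution 1.5 the spermatogonia-like share at ZT13 was 13.1%, the spermatocyte-like shares 30.0%, 32.6%, 29.3% and 19.96%, and the spermatid-like share at ZT7 25.2%. With at least 1000 UMIs the shares were 3.11%, 2.96%, 8.18% and 1.90% spermatogonia-like, 25.0%, 16.6%, 28.6% and 17.3% spermatocyte-like and 6.47%, 1.198%, 4.91% and 21.3% spermatid-like. With genes centred per library they were 2.33%, 28.7%, 5.35% and 1.09% spermatogonia-like, 22.6%, 23.6% and 13.1% spermatocyte-like at the first 3 times, and 15.1%, 11.4%, 15.5% and 27.8% spermatid-like. With doublets kept the spermatocyte-like shares were 29.7%, 33.0%, 27.9% and 25.4%, and the spermatid-like shares 9.99%, 26.5% and 9.82% at the first 3 times. The first naming form gave spermatocyte-like shares of 31.1%, 26.6%, 30.1% and 25.9%, with 18, 16, 14 and 12 Leydig-like cells and no Sertoli-like cells. Shallow clusters kept in their class gave 31.9%, 26.7%, 31.7% and 26.0% spermatocyte-like and 36.3%, 27.9%, 21.2% and 57.3% spermatid-like.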

Other observations

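Tests chosen only after the result was seen were those of class shares and of batch against time for the 12 h component, and both tests of the 6 genes of largest ratio; the tests of depth and of liver RNA were set before.

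The single genes of this paragraph were chosen after their values were seen. Some immediate early genes were highest at ZT7 and some heat shock genes at ZT19, but fosb, fosl2 and atf3 were highest at ZT19, hspb1 at ZT7, hsp90aa1.2 and dnajb1a at ZT13 and hsp90aa1.1 at ZT1. Over all cells, fosab was at 28.1 CPM at ZT1, 86.6 at ZT7, 37.9 at ZT13 and 65.6 at ZT19, jun at 15.7, 47.6, 22.7 and 21.7, junbb at 1.56, 19.4, 4.01 and 4.64, and egr1 at 1.73, 12.4, 1.86 and 3.42 CPM. The chaperone gene hsp70.2 was at 287, 214, 333 and 532 CPM, hsp70.3 at 346, 421, 420 and 718, and dnajb1b at 153, 266, 184 and 359 CPM. The dissociation and stress list lay at the 99.7th percentile of matched lists in 24 h amplitude over all cells, with 13 of 28 genes highest at ZT7 and 10 at ZT19, and at the 78.1th with cells thinned to 1000 UMIs. In the 12 h component, weighed below, it lay at the 99.9th percentile over all cells and at the 93.3th with thinned cells. In classes its 24 h amplitude lay at the 98.2th percentile or above, except fibroblast-like cells at the 19.5th. The Leydig-like, Sertoli-like and fibroblast-like values rest on few cells, 14 to 24, 8 to 25 and 2 to 11 per library. The ribosomal protein gene rpl26 was at 103, 1545, 515 and 468 CPM over all cells, and at 120, 1850, 562 and 657 CPM in spermatogonia-like cells.

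Of the other fixed lists over all cells, the axoneme list lay at or above all 10000 random lists, and the percentiles of the rest were 98.4 for intraflagellar transport, with cholesterol synthesis at 92.5, temperature-responsive RNA binding at 87.1, glycolysis at 82.1, germ-soma signals at 80.8, extracellular matrix at 79.3, ciliogenesis and spermiogenesis regulators at 58.6, piRNA pathway at 55.7, receptors at 45.7, retinoid metabolism at 43.7, homologous recombination repair at 30.7, S phase at 19.3, ribosomal proteins at 7.33, oxidative phosphorylation at 3.50 and G2 and M phase at 2.23. Several of these moved with the setting: intraflagellar transport was at 48.8 with thinned cells and 85.6 with equal weight to the 3 germ cell classes, cholesterol synthesis at 53.1 and 70.8, ciliogenesis and spermiogenesis regulators at 59.3 and 1.61, germ-soma signals at 62.9 and 28.7, extracellular matrix at 43.1 and 29.7, homologous recombination repair at 9.36 and 81.2, and receptors at 7.18 and 42.0. The G2 and M phase list was at 45.4 with thinned cells and at or above all random lists with equal weight. The axoneme list stayed at or above all random lists with thinned cells and with equal weight. It did so too inside spermatogonia-like and spermatocyte-like cells, and lay at 95.6 inside spermatid-like cells. These values argue against shares of the named classes as its whole cause, though the mix of clusters within a class was not held fixed. Shares of cell classes also differed between the libraries, so the percentiles over all cells describe the libraries.

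Over genes of all cells, the 12 h component, which sets ZT1 and ZT13 against ZT7 and ZT19, exceeded the mean 24 h component by a ratio of sums of squares of 2.33 (bootstrap interval over genes 2.11 to 2.61). Depth followed the same contrast, as median UMIs per cell were 6653 and 8193 at ZT1 and ZT13, and 4710 and 3719 at ZT7 and ZT19. With every cell thinned to 1000 UMIs the ratio was 1.93 (1.81 to 2.07), above the bound of 1.5 set beforehand. This argues against UMIs per cell as the whole cause, though genes are not independent replicates. Thinning cannot undo other differences in capture or library quality, which stay open. Shares of the named classes are argued against as the whole cause by the lowest ratio inside the 3 germ cell classes, 2.78, which was 1.67 (1.58 to 1.78) in spermatogonia-like cells once thinned. The mix of clusters within a class was not held fixed, and stays open. A difference in library preparation between these pairs and an effect of sampling time cannot be told apart with 1 library per time, so no biological explanation could be tested.

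Liver transcripts were most frequent at ZT19, where the transferrin gene tfa, chosen after its values were seen, was at 57.8 CPM at ZT1, 2.70 at ZT7, 0.266 at ZT13 and 234 at ZT19 over all cells. A candidate explanation is free RNA from liver tissue in the cell suspension, which the protocol names no sort to remove. Over 8 hepatocyte markers the median ratio of ZT19 to the highest other library was 2.71 in spermatogonia-like, 7.82 in spermatocyte-like and 9.03 in spermatid-like cells. ZT1 did not follow its liver transcripts: over all cells apoa2 was at 159 CPM there against 6.88 at ZT7, and fabp10a at 54.7 against 3.41. In spermatocyte-like cells apoa2 was at 2.79 against 3.11 CPM, fabp10a at 0.531 against 2.44 and tfa at 1.13 against 1.35. In spermatogonia-like cells apoa2 and tfa, and in spermatid-like cells tfa, were slightly higher at ZT1. Free RNA in proportion to each library's liver transcripts is thus not borne out at ZT1, and the explanation stays open. Expression by germ cells is argued against for the markers as a set by their order in these classes at ZT19, which followed that in hepatocyte-like cells with a Spearman correlation across the 8 genes of 0.857 or more; genes are not independent replicates. It stays open for fgb, at 6.30, 2.03, 8.08 and 4.96 CPM in spermatocyte-like cells and highest at ZT1 in spermatogonia-like cells, and for ambp, highest there at ZT13 with 1.41 CPM.

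For the 6 genes of largest ratio over all cells, 3 of 6 (apoa2, fabp10a and BX005351.1) had 1 highest and 1 lowest library in all germ cell classes. The first 2 are hepatocyte markers, weighed with the liver transcripts above. All libraries are labelled as AB strain, so a strain or animal variant, or another change of a whole library, stays open mainly for the last. The lowest median ratio inside a germ cell class was 1.97, in spermatogonia-like cells, and it was above 2 in the other 2 classes. These ratios carry a pseudocount of 5 CPM, which understates them, and apoa2, at 0.181 CPM at ZT13 and 12.5 CPM at ZT19 in spermatogonia-like cells, and fabp10a, at 0.218 and 5.84 CPM, changed inside the class, so shares of cell classes are not their whole cause. The ratios of apoa1b were 2.16 in spermatogonia-like, 3.84 in spermatocyte-like and 5.70 in spermatid-like cells, so shares are not its whole cause either. BX005351.1 had 16.6 in spermatid-like cells, so it too changed inside a class, but 1.85 in spermatogonia-like and 1.44 in spermatocyte-like cells. The mix of clusters within a class was not held fixed. For the remaining genes, whose highest ratio inside a class was 1.94, shares stay open. No biological explanation was tested.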
